A study of Homo sapiens with 6 samples.

How the data were processed

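RNA sequencing was analysed for 6 libraries of T24 cells, 3 of the NC group and 3 of the sh-circRIMS1 group. Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was depleted, linear RNA was digested with RNase R and strand-specific libraries were made with a KAPA kit. Linear messenger RNAs were nevertheless abundant in the deposited values, with GAPDH and RPLP1 among the highest genes, so whether the RNase R step applied to these libraries is unclear. The authors deposited 1 table of FPKM, with 6 FPKM columns, gene symbols, NCBI GeneIDs and Gene Ontology and KEGG terms. Per the submitters' processing notes, Trimmomatic, HISAT2, Cufflinks, HTSeq, DESeq and StringTie were used, and their versions, roles and settings, the genome build and the handling of reads shared between gene copies are not given in the sources used here. No coordinates are printed for that reason. The knockdown columns carry an si prefix where the sample titles carry an sh prefix. They were matched to the titles by the circ name and the number, and whether a small interfering RNA or a short hairpin RNA was used remains open.

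The table held 20030 gene rows, of which 3813 were 0 in every library. Current symbols were found for 19741 rows through their GeneIDs, and the symbols printed are those of the table. FPKM values are already divided by sequencing depth and transcript length, so no count model was used. Absolute depth is unknown. Genes with FPKM below 0.3 step in multiples of the value of a single read, and ratios of such values placed the depth of NC replicates 2 and 3 at 1.17 and 1.01 times that of NC replicate 1. The same ratios were 1.05, 1.03 and 1.09 for sh-circRIMS1 replicates 1, 2 and 3. Ratios far from equal depth were left out first, so a large difference in depth could not have been found. Between 31.7% and 46.5% of the ratios kept lay within 2% of the chosen step, so these depths are estimates. An FPKM of exactly 0 is reported as listed at 0. FPKM of a gene family with near-identical copies or pseudogenes, such as ribosomal protein, histone, HLA and metallothionein genes, can depend on how shared reads were counted and is uncertain to that extent.

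Genes with a mean FPKM of at least 1 over the 6 libraries were tested, which left 10408. The comparison was made with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with an intensity trend in the empirical Bayes step, group as the only term and Benjamini-Hochberg adjustment at 0.05, two-sided. Changes are sh-circRIMS1 minus NC on this scale, which understates the change of low genes. RIMS1 and RTL1 lay below the filter and were given an exact two-sided permutation test of 3 against 3 libraries, whose smallest possible p is 0.1. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry were run beside it. With the preset correlation, splits of the libraries that mixed the groups called 7 to 12 lists. Such a call alone therefore does not mark a difference between the groups. Annotation terms of 10 to 500 tested genes were tested with a one-sided Fisher's exact test for higher and for lower genes, against the 9681 tested genes with any term. The groups, the tests, 29 gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

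The text names the genes of the design, the 12 largest rises and 12 largest falls among called genes with FPKM above 0 in every library and groups that did not overlap, and up to 4 called members per list with the smallest p, though not every gene that met the rule is printed. Where no member of a list passed, up to 2 members with the highest mean FPKM were named. Reported miR-433-3p targets that passed were all named. Genes outside this rule were chosen after their values were seen, and are given in the closing part as such. Lists of genes not represented in the table rows used here were mitochondrially encoded mRNAs, structured non-coding RNAs and nuclear long non-coding RNAs, each with 0 members. MIR433 and MEG3 were likewise not analysed here. A planned test of genes with miR-433-3p seed matches in their 3′ UTRs was not run, since no 3′ UTR sequences were used here.

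The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which can be technical. In data simulated for this comparison over 10408 genes, the gene test recovered 87% of 100 genes changed by 1 on the log2 scale and 43% of 100 genes changed by 0.5. It called 0.0983% of 10178 unchanged genes. The simulated noise was independent between genes and equal in spread in both groups, and far fewer genes were changed than were called in the data. These rates may therefore not carry over to the data. Alternatives covered the pseudocount (0.1 and 1), the filter (none, and a mean FPKM of at least 5), the scaling between libraries (median of ratios, quantile normalization and rescaling to TPM), the variance model, array weights, a replicate block, a fold minimum, the 10350 tested genes that the gene reference lists as protein-coding, the set test, the enrichment background and the removal of each library in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.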

Results

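T24 cells, a line established from a human urinary bladder carcinoma, were profiled by RNA sequencing in an NC group and a group labelled as a knockdown of circRIMS1, a circular RNA named after its host gene RIMS1, with 3 libraries each. The series title presents circRIMS1 as a sponge for the microRNA miR-433-3p that promotes bladder cancer progression through CCAR1, and the design asks which messenger RNAs differ between the 2 groups. FPKM summed to between 268143 in sh-circRIMS1 replicate 2 and 284682 in sh-circRIMS1 replicate 3. The number of genes above 0 was 14078, 14199 and 14091 in the NC libraries and 14743, 14906 and 14834 in the sh-circRIMS1 libraries. Across genes, which are not independent replicates, Pearson's r of log2 values was 0.997 between NC replicates 1 and 2, 0.997 between sh-circRIMS1 replicates 1 and 3, and 0.974 and 0.975 between sh-circRIMS1 replicate 2 and the other two. Between groups it ran from 0.946 to 0.959. The first principal component held 76.8% of the variance and separated the groups, and the second held 18.1% and set sh-circRIMS1 replicate 2 apart.

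CCAR1, which encodes a regulator of cell division and apoptosis and a coactivator of transcription, fell in the sh-circRIMS1 cells to 52.6% of its NC level. Its FPKM was 23.2 ± 0.741 (SD, n = 3) in NC and 12.2 ± 1.4 (SD, n = 3) in sh-circRIMS1, with 22.4, 23.7 and 23.6 in the NC libraries and 12.5, 10.7 and 13.4 in the sh-circRIMS1 libraries. The log2 change was -0.91 with a standard error of 0.09 and a 95% interval from -1.12 to -0.69 (limma adjusted p = 0.000635), and the exact permutation p was 0.1, the smallest that 3 against 3 libraries can give. Among called genes, 59 fell further than CCAR1. RIMS1, which encodes a scaffold protein of presynaptic active zones, stood at 0.436 ± 0.0579 FPKM (SD, n = 3) in NC and 0.257 ± 0.0456 FPKM (SD, n = 3) in sh-circRIMS1, with an exact permutation p of 0.1. Values per gene cannot tell circular from linear RNA, so this is no measure of circRIMS1, and the knockdown itself was not measured here.

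CCAR2, the paralog of CCAR1, measured 19.5 ± 0.873 FPKM (SD, n = 3) in NC and 17.5 ± 2.58 FPKM (SD, n = 3) in sh-circRIMS1, a difference within the replicate spread (limma adjusted p = 0.283). RTL1, a retrotransposon-derived gene at the imprinted locus that also holds the miR-433 gene, was listed at 0.0101, 0 and 0 FPKM in the NC libraries and at 0.259, 0.259 and 0.138 FPKM in the sh-circRIMS1 libraries. Whether reads were counted by strand is not given in the sources used here, so RTL1 reads cannot be separated from those of RNAs made from the opposite strand.

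**Figure D1:**
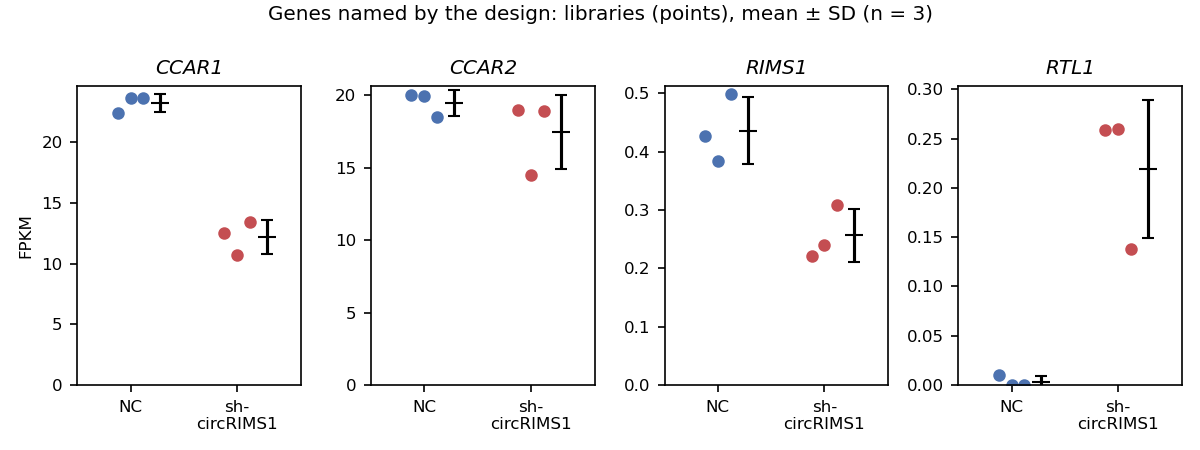
FPKM of CCAR1, CCAR2, RIMS1 and RTL1 in each NC (blue) and sh-circRIMS1 (red) library, with the mean ± SD of 3 libraries beside the points and a separate axis from 0 for each gene. The sh-circRIMS1 libraries lie below the NC libraries for CCAR1 (12.2 against 23.2 on average) and RIMS1 (0.257 against 0.436), while the groups overlap for CCAR2.

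The largest rises included genes of the antiviral interferon response. MX1, a dynamin-like GTPase that blocks viral replication, rose from 0.571 ± 0.0405 to 82.0 ± 36.7 FPKM (SD, n = 3 each), a log2 change of 6.14 with a standard error of 0.35 (limma adjusted p = 0.000114). IFI27, an interferon-induced mitochondrial protein, rose from 14.3 ± 0.507 to 583 ± 172 FPKM (SD, n = 3 each). IFI6, IFI44L, OAS1, RSAD2, TRIM22, OAS2, CMPK2, XAF1 and MX2 rose by 5.93, 5.43, 4.69, 4.52, 4.43, 4.41, 4.11, 3.79 and 3.63 on the log2 scale, and the chemokine CCL5 by 4.35.

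Over all 10408 tested genes 2598 were higher and 1322 lower, shares against which the list counts here and below are to be read. All 32 tested members of the interferon response list were higher in sh-circRIMS1, and 32 were higher when adjusted over the list alone. The list median changed by 3.16 on the log2 scale (camera adjusted p = 5.92e-16; adjusted p = 0.368 with an estimated correlation). The transcription factor subunit IRF9 rose from 10.2 ± 0.742 to 36.9 ± 0.978 FPKM, and the helicase-related DDX60 from 1.49 ± 0.133 to 16.5 ± 1.1 FPKM (SD, n = 3 each). The rise was smaller in sh-circRIMS1 replicate 2, where the list median lay 2.44 above the NC mean, against 3.62 and 3.64 in replicates 1 and 3. Without replicate 2 all 32 members were still higher, with a list median of 3.63. Over all genes, 3803 of 10340 tested genes were then higher and 2474 lower. In the leukocyte list CD68, a lysosomal glycoprotein of macrophages and other cells, rose from 4.57 to 18.2 FPKM as the only tested member, and the median of the 12 markers was 0 in NC and 0.0113 FPKM in sh-circRIMS1.

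**Figure D2:**
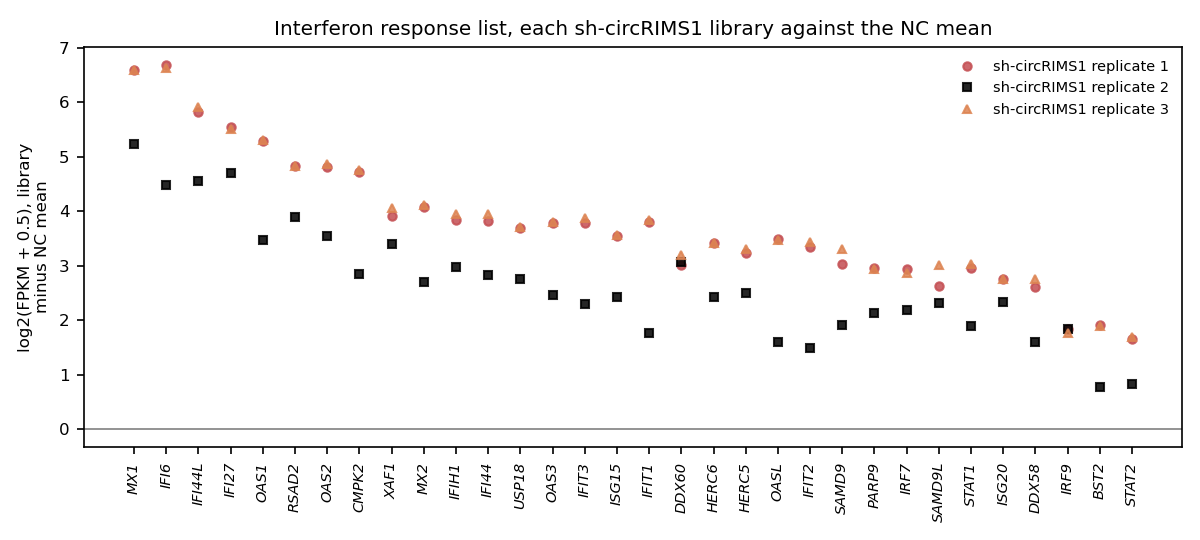
Change of each of the 32 tested interferon response genes in each sh-circRIMS1 library, as log2(FPKM + 0.5) minus the mean of the 3 NC libraries, with genes ordered by mean change. All points lie above 0, and replicate 2 (squares) lies below replicates 1 and 3 for most genes, with list medians of 2.44, 3.62 and 3.64.

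Inflammatory and growth-responsive genes also rose. In the NF-kB and inflammatory cytokine list 13 of 22 tested members were higher, 0 lower and 9 not past the threshold, with 14 higher when adjusted over the list alone (camera adjusted p = 0.000196; adjusted p = 0.229 with an estimated correlation). The granulocyte-macrophage growth factor CSF2 rose from 1.47 to 17.4 FPKM, IL6 from 8.70 to 32.7 FPKM, and TNFAIP3, a feedback inhibitor of NF-kB, from 9.33 to 18.9 FPKM. Of 25 immediate early genes 14 were higher and 0 lower, and 16 were higher when adjusted over the list alone (camera adjusted p = 0.00346; adjusted p = 0.231 with an estimated correlation). KLF4 rose from 12.5 to 58.7 FPKM and JUNB from 29.2 to 82.3 FPKM, while NR4A1 and IER2 rose by 0.89 and 0.54 on the log2 scale. Without sh-circRIMS1 replicate 2 the immediate early genes had 19 members higher and 3 lower. The NF-kB and inflammatory cytokine list then had 19 higher and 1 lower, and its median went from 0.60 to 0.41.

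Genes of apoptosis and of the p53 response rose in part. In the apoptosis list 13 of 24 tested members were higher, 2 lower and 9 not past the threshold, with 14 higher and 2 lower when adjusted over the list alone. PMAIP1 and BMF, both pro-apoptotic BH3-only genes, rose from 83.8 to 229 FPKM and from 0.814 to 3.72 FPKM, and the initiator caspase CASP8 rose by 0.62 on the log2 scale. The camera adjusted p of 0.0339 became 0.231 with an estimated correlation, and the call was lost without a filter, at a mean FPKM of at least 5, and without NC replicate 3 or sh-circRIMS1 replicate 1. Among 22 p53 targets 9 were higher and 2 lower, with 12 higher and 2 lower when adjusted over the list alone, and the list was not called (camera adjusted p = 0.134; adjusted p = 0.488 with an estimated correlation) except by fry (adjusted p = 0.00381). CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 38.9 to 82.3 FPKM, FAS and TP53INP1 rose by 1.25 and 1.28 on the log2 scale, and the DNA polymerase POLH fell by 0.72. Without sh-circRIMS1 replicate 2 the counts were 13 higher and 5 lower.

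Genes of mitosis and protein synthesis were lower. In the G2/M and mitosis list 19 of 26 tested members fell and 0 rose, with 21 lower when adjusted over the list alone and a list median of -0.48 (camera adjusted p = 1.69e-11; adjusted p = 0.231 with an estimated correlation). BIRC5, which encodes survivin, a protein of cytokinesis and cell survival, fell from 39.8 to 22.2 FPKM, the mitotic kinase PLK1 from 42.0 to 27.2 FPKM, KIF11 from 35.6 to 22.6 FPKM and KIF23 from 23.9 to 15.3 FPKM. Of 50 cytosolic ribosomal protein genes 33 fell and 0 rose, with 35 lower when adjusted over the list alone and a list median of -0.22 (camera adjusted p = 6.75e-14; adjusted p = 0.231 with an estimated correlation). RPLP0 fell from 1083 to 685 FPKM, RPL7 from 648 to 412 FPKM, RPS6 from 716 to 469 FPKM and RPL6 from 233 to 148 FPKM. Under quantile normalization 24 ribosomal protein genes were lower and 3 higher, and the list median was -0.14.

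The list of ribosome biogenesis and MYC targets had 7 of 29 members lower and 0 higher, and 5 lower when adjusted over the list alone (camera adjusted p = 0.000271; adjusted p = 0.583 with an estimated correlation). NPM1, DKC1, RRS1 and NOP58 fell by 0.24, 0.31, 0.25 and 0.36 on the log2 scale. The call of NOP58 was lost without NC replicate 1, 2 or 3 or sh-circRIMS1 replicate 3 and that of RRS1 without NC replicate 2 or 3. Without sh-circRIMS1 replicate 2, 14 members were lower and 4 higher, and the list median went from -0.21 to -0.08. Of 25 DNA replication and G1/S genes 3 were lower and 1 higher, and 2 were lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.000944; adjusted p = 0.650 with an estimated correlation). The share of lower members was near that of all tested genes, 1322 of 10408. TYMS fell from 88.7 to 65.3 FPKM and RRM2 from 66.5 to 45.3 FPKM, both calls lost without any 1 of the NC replicates, whereas CCNE1, the G1/S cyclin, rose from 5.18 to 8.99 FPKM. All 25 members lay lower in sh-circRIMS1 replicate 2 than in the mean of replicates 1 and 3, and without that library the list median went from -0.29 to -0.07. In that fit 10 members were lower and 1 higher, and the list was still called by camera.

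Of the 12 largest falls, that of CPA4, a secreted carboxypeptidase, was 2.83 on the log2 scale, and the adhesion protein AMIGO2 fell by 2.57, from 49.4 ± 0.738 to 7.98 ± 1.53 FPKM (SD, n = 3 each). CTGF, the matricellular growth factor now named CCN2, fell from 112 ± 1.45 to 26.0 ± 1.41 FPKM (SD, n = 3 each), a log2 change of -2.09 with a standard error of 0.06 (limma adjusted p = 7.25e-06). PPME1, a methylesterase of protein phosphatase 2A, fell from 148 ± 1.96 to 38.4 ± 6.95 FPKM (SD, n = 3 each). IGFBP5, TAGLN, RELN, NOG, COL13A1, KRT80, TLE4 and SLC6A9 fell by 2.11, 1.99, 1.61, 1.59, 1.57, 1.54, 1.49 and 1.36 on the log2 scale.

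Of 21 YAP/TEAD targets 8 were lower and 5 higher, also when adjusted over the list alone. CTGF and CRIM1 fell, the latter from 45.2 to 27.6 FPKM, whereas the coagulation factor gene F3 rose from 118 to 271 FPKM and NT5E, an ectonucleotidase, from 51.9 to 88.7 FPKM. The camera adjusted p of 0.0261 became 0.231 with an estimated correlation, and the call was lost under quantile normalization and at a mean FPKM of at least 5. Without sh-circRIMS1 replicate 2, 14 targets were lower and 5 higher. Of 25 listed epithelial and urothelial genes 7 were tested and the others lay below the filter. Of the 7, 3 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.00672; adjusted p = 0.231 with an estimated correlation). KRT7 fell from 436 to 298 FPKM, KRT18 from 516 to 372 FPKM and PPARG from 2.75 to 1.89 FPKM, and 5 members were lower without sh-circRIMS1 replicate 2. The median of this list relative to all tested genes turned to 0.10 when genes below the filter were included.

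Among 16 mesenchymal and EMT genes 5 were higher and 5 lower, with 5 higher and 6 lower when adjusted over the list alone. SNAI2, a transcriptional repressor of epithelial genes, rose from 6.02 to 19.1 FPKM, while TAGLN and CTGF fell. The list median was 0.16, the camera direction was down (adjusted p = 0.617; adjusted p = 0.682 with an estimated correlation), and the median turned to -0.20 under quantile normalization. Of 5 endothelial markers 4 were higher, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.0848; adjusted p = 0.622 with an estimated correlation). It was called by fry (adjusted p = 0.0150), under quantile normalization (camera adjusted p = 0.0293) and without sh-circRIMS1 replicate 3. Without sh-circRIMS1 replicate 2 the list had fewer than 5 tested members and gave no result. TIE1 rose from 0.133 to 2.70 FPKM, ESAM from 0.790 to 2.50 FPKM, ROBO4 from 7.62 to 14.3 FPKM and EGFL7 from 25.9 to 36.8 FPKM, and all 5 markers lay higher in sh-circRIMS1 replicate 2 than in the mean of replicates 1 and 3. The single tested fibroblast marker FBLN1 measured 43.8 and 42.0 FPKM (limma adjusted p = 0.390). Among 3 tested markers of kidney-derived packaging cells, LHX1 fell from 13.7 to 8.33 FPKM and no other passed.

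**Figure D3:**
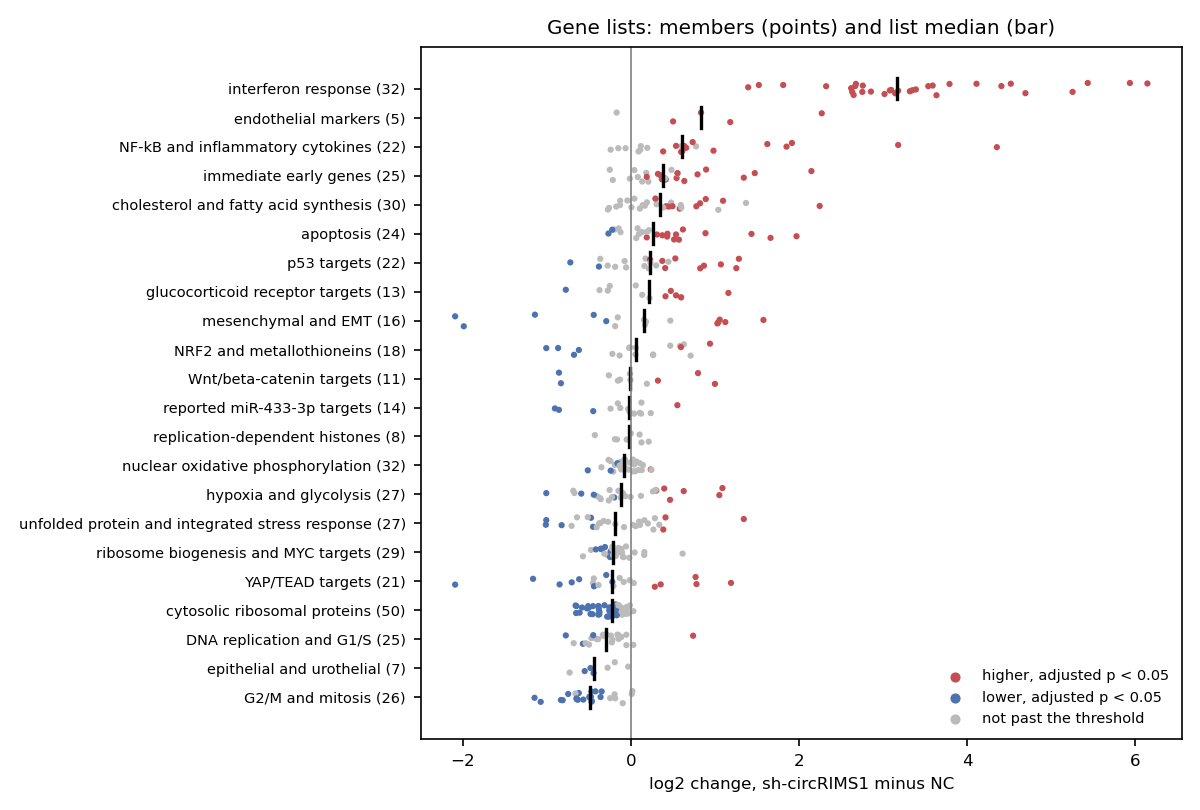
Log2 change, sh-circRIMS1 minus NC, of each tested member of the 22 gene lists (points, red higher, blue lower, grey not past an adjusted p of 0.05), with the list median as a black bar and the number of members in brackets. The interferon response list lies apart with a median of 3.16, and the G2/M and mitosis list has the lowest median at -0.48.

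The reported miR-433-3p targets were not called as a group. Of 14 tested genes 3 were lower, 1 higher and 10 not past the threshold, with the same counts when adjusted over the list alone (camera adjusted p = 0.207; adjusted p = 0.488 with an estimated correlation). Besides CCAR1, the Wnt inhibitor DKK1 fell from 87.9 to 49.3 FPKM and TYMS, thymidylate synthase, from 88.7 to 65.3 FPKM, whereas HDAC6, a cytoplasmic deacetylase, rose from 4.22 to 6.41 FPKM. Without sh-circRIMS1 replicate 2, 6 targets were lower and 2 higher, and the list was again not called (camera adjusted p = 0.0628). Of 21 listed Wnt/beta-catenin targets 11 were tested and the others lay below the filter. Of the 11, 3 were higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.536, or 0.682 with an estimated correlation). EPHB2 and FOSL1 were higher, the latter not without NC replicate 1 or 2, and BIRC5 and DKK1 lower. The median of this list, -0.01, was opposite in sign to its mean, which was close to 0 at 0.00412. It turned to 0.01 after rescaling to TPM, and without replicate 2 the counts were 3 higher and 5 lower.

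Among metabolic and stress lists, counts of calls moved with sh-circRIMS1 replicate 2. The counts over all genes moved too. Without that library 3803 of 10340 tested genes were higher and 2474 lower, against 2598 and 1322 of 10408 with it. A larger count within a list without replicate 2 is therefore not particular to that list. Of 30 cholesterol and fatty acid synthesis genes 10 were higher and 0 lower, also when adjusted over the list alone (camera adjusted p = 0.102; adjusted p = 0.682 with an estimated correlation). STARD4, a sterol carrier, rose from 0.536 to 4.48 FPKM, and TM7SF2, HSD17B7 and SC5D rose by 0.89, 0.58 and 0.42 on the log2 scale, SC5D not under quantile normalization. The list median lay 0.54 and 0.51 above the NC mean in replicates 1 and 3 and -0.03 from it in replicate 2, and without replicate 2 the list had 24 members higher and 1 lower, with a median of 0.53. It was then called by camera, as with array weights and under quantile normalization. Of 27 genes of the unfolded protein and integrated stress response 3 were higher and 5 lower, also when adjusted over the list alone (camera adjusted p = 0.127; adjusted p = 0.682 with an estimated correlation). The serine synthesis enzymes PSAT1 and PHGDH fell from 328 to 164 FPKM and from 32.0 to 22.9 FPKM, ATF4 fell from 113 to 82.7 FPKM, a call lost without NC replicate 3, and the chaperone HSP90B1 rose from 119 to 156 FPKM. In replicate 2, 21 of the 27 lay above the mean of replicates 1 and 3, and without it 17 were lower and 8 higher, with a median of -0.30 and a call by camera, as with array weights and no filter.

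Of 27 hypoxia and glycolysis genes 6 were higher and 4 lower, also when adjusted over the list alone (camera adjusted p = 0.181; adjusted p = 0.583 with an estimated correlation), with SLC2A3, ALDOC and P4HA1 higher by 1.09, 1.05 and 0.46 on the log2 scale and ADM lower at -1.01. Without replicate 2 this list had 7 members higher and 15 lower and was called by camera. Of 13 glucocorticoid receptor targets 5 were higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.590; adjusted p = 0.682 with an estimated correlation). KLF9, NFKBIA and FKBP5 rose by 1.16, 0.60 and 0.47, the last to 0.18 and without a call under quantile normalization, and SGK1 fell by 0.78, and without replicate 2 the counts were 6 higher and 4 lower. Of 18 NRF2 and metallothionein genes 2 were higher and 4 lower, with 3 and 5 when adjusted over the list alone, a median of 0.06 and a downward camera direction (adjusted p = 0.617; adjusted p = 0.682 with an estimated correlation) that turned upward under quantile normalization. Fry called this list upward (adjusted p = 0.00765). The median was -0.02 after median-of-ratios scaling, and without replicate 2 the counts were 5 higher and 7 lower. MT1X and FTH1, which bind metal ions and store iron, rose by 0.94 and 0.59, while TXNRD1 and NQO1 fell by 0.68 and 0.87, the call of NQO1 being lost without any 1 of the NC replicates. Of 32 nuclear oxidative phosphorylation genes 1 was higher and 3 lower, with 1 and 1 when adjusted over the list alone (camera adjusted p = 0.0697; adjusted p = 0.682 with an estimated correlation), and ATP5PB, ATP5PO and NDUFB8 fell by 0.51, 0.24 and 0.16 while NDUFB5 rose by 0.23. Over 18 alternatives the call of NDUFB8 was lost in 8 and those of ATP5PO and NDUFB5 in 4 each, removal of NC replicates among them. The list was called downward in 5 of its 19 alternatives, among them median-of-ratios scaling (camera adjusted p = 0.0385) and no filter. Without replicate 2 the list had 9 members higher and 5 lower, and its median went from -0.08 to 0.02. With all 6 libraries none of the 8 replication-dependent histone genes passed, by limma over all genes, over the list alone or at an unadjusted p under 0.05 (0 genes), with HIST1H2BK at 14 and 11.4 FPKM and HIST1H1C at 6.48 and 6.88 FPKM. The camera adjusted p of the list was 0.536 (adjusted p = 0.766 with an estimated correlation). All 8 lay lower in sh-circRIMS1 replicate 2 than in the mean of replicates 1 and 3, and without replicate 2, 5 were higher and 0 lower, with a list median of 0.36.

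Annotation terms of the higher genes were led by type I interferon signaling, with 32 of 35 tested genes higher (3.68 times the expected number, Fisher's exact test, adjusted p = 2.17e-13), followed by interferon-gamma-mediated signaling with 24 of 28, defense response to virus with 54 of 96 and lysosome with 57 of 111 (adjusted p = 7.09e-07). Cytokine receptor interaction had 43 of 81 genes higher. Terms of the lower genes were led by translational initiation, with 35 of 64 genes lower (4.31 times the expected number, adjusted p = 1.84e-12), and included focal adhesion with 65 of 212, cell division with 69 of 232 and the condensed chromosome kinetochore with 29 of 76. In all, 49 terms were enriched among higher genes and 63 among lower genes out of 1978 tested in each direction. The ribosome pathway, with 46 of 130 genes lower, was not enriched under quantile normalization (Fisher's exact test, adjusted p = 0.275, against 2.65e-13 after median-of-ratios scaling).

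Counted over all genes, 3920 of 10408 passed the limma test, 2598 higher and 1322 lower, and 407 of the higher and 45 of the lower genes changed by at least 1 on the log2 scale. The groups did not overlap for 5987 tested genes, or 57.5%, against 10% by chance. The 2602 tested genes with the lowest mean level had a median change of 0.24 and the 2602 with the highest -0.07. The balance of directions depended on the scaling between libraries: 66.3% of calls were higher with FPKM as deposited, 51.8% (2074 higher, 1930 lower) after median-of-ratios scaling and 43.2% (1588 higher, 2085 lower) after quantile normalization, which moved the median change of all tested genes from 0.063 to -0.053. With the preset correlation 10 of the 22 lists were called by camera, against 0 with an estimated correlation, where 3 had an unadjusted p under 0.05, and 11 by fry, which did not call the DNA replication and ribosome biogenesis lists and called the p53, NRF2 and endothelial lists. Splits that mixed the groups called 7 to 12 lists with the preset correlation. Without NC replicate 1, 2 or 3 the calls numbered 2320, 2340 and 2323, and without sh-circRIMS1 replicate 2 they numbered 6277, with 3803 higher and 2474 lower.

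**Figure D4:**
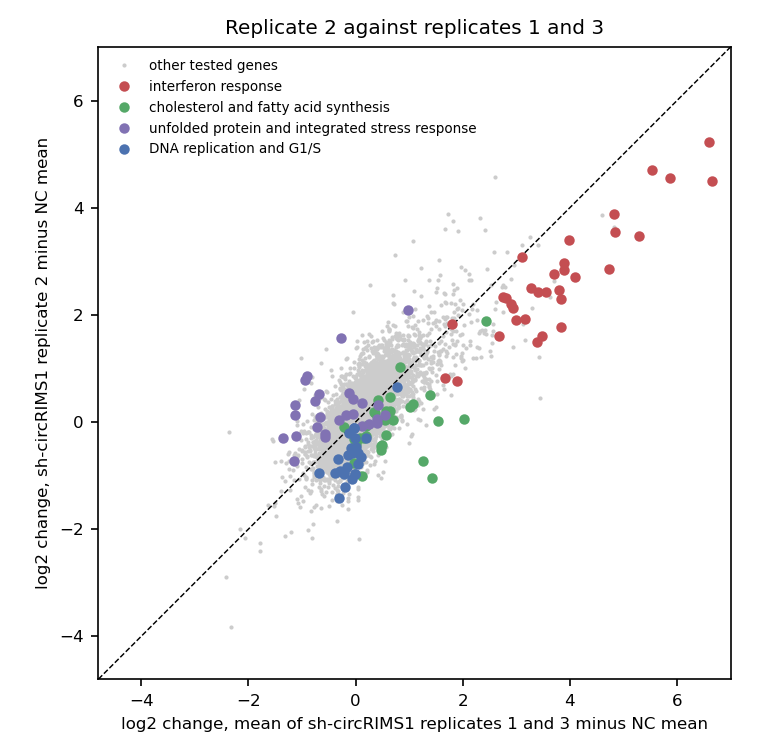
Log2 change against the NC mean in sh-circRIMS1 replicate 2 (y axis) and in the mean of replicates 1 and 3 (x axis) for each of the 10408 tested genes, with 4 gene lists in colour and the line of equal change dashed. Interferon response, cholesterol and DNA replication genes lie mostly below the line, by medians of -1.09, -0.53 and -0.58, and stress response genes mostly above it, by a median of 0.49.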

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

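The tests on replicate 2, on the interferon response and on low genes were chosen only after the result was seen; the splits of the samples were planned.

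A signal in genes that the comparison left out stood out: 156 genes below the filter were listed at 0 in every NC library and above 0 in every sh-circRIMS1 library, against 8 genes the other way. Their median was 0.0397 FPKM in sh-circRIMS1, with GBP5, an interferon-induced GTPase, highest at 1.22 FPKM, STATH, a salivary calcium-binding protein, at 0.565 FPKM and the interferon gene IFNL2 at 0.419 FPKM. Moderately deeper sequencing was argued against by relative depth, which was 0.994 times that of NC in the mean. A large difference in depth would have escaped that estimate. Reads from genomic DNA were weighed with 400 olfactory receptor genes, whose mean rose from 0.00095 to 0.0033 FPKM. That gain was 2.12% of the median gain of 2801 genes with a mean FPKM of 0.05 to 1. It argues against genomic reads for those 2801 genes only. Most of the 156 genes lay below that range, and the olfactory receptor gene OR1J2 was among the 156 at 0.0276 FPKM. For the 156, which were picked for values above 0, the comparison does not decide. Wider low transcription in sh-circRIMS1 cells remains a hypothesis that was not tested here. Differences between libraries in ribosomal RNA depletion or in the RNase R step were not tested either, so a technical origin stays open. Rises were also more frequent among the lower of the tested genes, which hold none of the 156. There a single scaling factor as the whole cause was argued against by the difference of 0.32 on the log2 scale between the median changes of the lowest and highest genes. Median-of-ratios scaling, with a single factor per library, lowered the number of tested genes called higher from 2598 to 2074. Quantile normalization, which varies with the level of a gene, lowered it to 1588. Scaling of either kind stays open for part of those rises.

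The interferon response rose in all 3 sh-circRIMS1 libraries. Immune cells in the cultures were argued against by 12 leukocyte markers, whose median was 0.0113 FPKM and of which 10 lay below 0.1 FPKM, while CD68 rose from 4.57 to 18.2 FPKM and CD14 measured 0.903 FPKM in NC and 1.04 FPKM in sh-circRIMS1, and the interferon list rose by 3692 FPKM, or 1.33% of all FPKM. Scaling was argued against by a list median of 3.14 under quantile normalization. Loss of circRIMS1 and a response of the cells to the introduced RNA cannot be told apart. The labels name 1 target and no rescue, and do not say whether the numbers of the knockdown samples mark replicates or separate constructs. Either loss of circRIMS1 or a response to the introduced RNA could raise interferon genes. Constructs known to share no sequence would be the test.

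Replicate 2 of sh-circRIMS1 stood apart from replicates 1 and 3, with 114 tested genes over 2-fold higher and 96 over 2-fold lower, against 8 genes over 2-fold apart between replicates 1 and 3. Of the genes that fell 2-fold in replicates 1 and 3, 15 of 54 (27.8%, 95% interval 16.5% to 41.6%) lay still lower in replicate 2. That interval counts genes as independent replicates, which they are not, and the bound for this share was set after the values were seen. The share alone therefore does not decide on mixing with NC cells or RNA. Mixing as the only cause was argued against by the 210 genes that were 2-fold apart, of which 158 lay outside the range of the other 5 libraries. These genes were picked for lying apart from replicates 1 and 3, so mixing together with another difference stays open. Shallower sequencing was argued against by 55 of the 2602 highest genes being over 2-fold apart, against 0 between replicates 1 and 3. A difference in construct, culture state, time of harvest or library preparation may remain. No such explanation was tested, since the labels do not describe these for single libraries.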

How the results depend on the processing

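The tests of annotation terms without each library and the replicate block with no filter were chosen only after the result was seen; the other alternatives were fixed before. CCAR1 stayed lower and past the threshold under its 18 alternatives (log2 change -0.97 to -0.82 without 1 library). Over named genes, 599 calls were the same, 28 weaker and 2 reversed when a library was left out, and 1225 were the same, 9 weaker, 2 stronger and 1 reversed under other settings. The cause was not tested except where fewer genes or libraries explain a count. The number of genes changed between sh-circRIMS1 and NC was 3920 (2598 higher, 1322 lower) and 2592 (1469 higher) at a mean FPKM of at least 5, where fewer genes were tested, 1588 higher and 2085 lower after quantile normalization, 6407 (3983 and 2424) with array weights, and 452 (407 and 45) with an absolute log2 change of at least 1. Without 1 library they ran from 2320 (without NC replicate 1) to 6277 (without sh-circRIMS1 replicate 2), higher genes from 1630 to 3803, lower genes from 685 to 2474, enriched terms from 24 to 75 among higher genes and from 30 to 59 among lower genes. Terms of lower genes with an absolute log2 change of at least 1 numbered 4. By camera 10 lists were called, against 0 with an estimated correlation (3 at an unadjusted p under 0.05; fry 11).

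The RIMS1 log2 change was -0.31 and ran from -0.59 with a pseudocount of 0.1 to -0.19 with one of 1, with a limma adjusted p of 0.0219 with no filter on low values and a log2 change of -0.31 (limma adjusted p = 0.0322) with the replicate block and no filter, against an exact p of 0.1. It has no value at a mean FPKM of at least 5, after quantile normalization or under the variance models and weights. The replicate block called 3138 genes (2142 higher, 996 lower), of which 3069 were shared with the fit without it. Deviations of same-numbered libraries correlated at -0.026, -0.0033 and -0.040, which shows no sign of pairs. So few libraries cannot exclude pairing, and the labels do not say whether same-numbered libraries were paired. The seed-site test and its alternatives were not run.

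List medians relative to all tested genes changed sign for epithelial and urothelial genes (0.10 with no filter), mesenchymal and EMT genes (-0.18 at a mean FPKM of at least 5, -0.15 after quantile normalization, -0.024 to 0.11 without 1 library), NRF2 and metallothionein genes (0.21 after quantile normalization, -0.054 to 0.037 without 1 library), nuclear oxidative phosphorylation (0.022 after quantile normalization) and replication-dependent histones (0.27 with array weights, -0.31 to 0.30 without 1 library). The HIST1H1C log2 change was 0.38 with array weights and -0.29 to 0.42 without 1 library, and the HIST1H2BK log2 change -0.71 to 0.054. In each range of the histones the highest value came without sh-circRIMS1 replicate 2. Absolute depth is unknown, which limits what can be said of genes at low FPKM.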

Other observations

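The tests of the gene groups in this part were chosen only after the result was seen, apart from the splits of the samples.

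Genes of antigen presentation by MHC class I rose together. All 15 of a list of 15 such genes were higher in sh-circRIMS1, 14 of them under median-of-ratios scaling and quantile normalization and 15 without sh-circRIMS1 replicate 2. The list was drawn up after the values were seen, so its count is no test. The deposited annotation term antigen processing and presentation had 19 of 37 genes higher (Fisher's exact test, adjusted p = 0.0258) and 4 lower. HLA-B rose from 14.8 to 153 FPKM (log2 change 3.33, standard error 0.07, limma adjusted p = 3.71e-06), HLA-F by 2.69, HLA-C by 2.08, and B2M, the shared light chain, from 343 to 931 FPKM. The HLA genes are similar in sequence, so their single values are uncertain. Among interferon genes below the filter, IFNL1 was listed at 0.154, 0.0661 and 0.0774 FPKM in NC and at 2.05, 0.378 and 2.40 FPKM in sh-circRIMS1, and IFNB1 at 0 in NC and at 0.306, 0 and 0.197 FPKM in sh-circRIMS1. IFNL2 and IFNL3 had means of 0 in NC and of 0.419 and 0.254 FPKM in sh-circRIMS1, IFNE of 0.148 and 0.119 FPKM, and IFNA1 and IFNG were listed at 0 in both groups. IFNL1 and IFNB1 were lowest in replicate 2 among the sh-circRIMS1 libraries, as was the median of the interferon response list.

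Among amino acid carriers, SLC38A2, a neutral amino acid carrier, fell from 399 to 170 FPKM (log2 change -1.23, limma adjusted p = 2.66e-05), and SLC38A1 and SLC7A5 each fell by 1.12. Of 12 heat shock genes 3 were lower (HSPA8, DNAJB1 and HSPD1), and 9 without replicate 2. Among Wnt/beta-catenin targets below the filter, SP5 measured 0.499 and 1.41 FPKM in NC and sh-circRIMS1, LEF1 0.609 and 1.00 and TCF7 0.247 and 0.556. AXIN2 measured 0.0514 and 0.141 FPKM and NKD1 0.00508 and 0.0562 FPKM, and the groups overlapped for none of these genes. NOTUM, NKD2, RNF43, LGR5 and MMP7 showed no such rise. Rises were frequent among low genes as a whole, so no conclusion is drawn.

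Single genes set sh-circRIMS1 replicate 2 apart from the mean of replicates 1 and 3. Among integrated stress response genes DDIT3 measured 29.9 against 8.0 FPKM, CHAC1 17.5 against 4.79, TRIB3 137 against 50.3 and SESN2 31.1 against 9.0, while the lipid synthesis genes SCD and INSIG1 measured 7.76 against 45.0 and 4.60 against 19.6 FPKM. Among heat shock genes HSPA8 measured 104 against 267 FPKM, and HSPA1A, HSPA1B, DNAJA1 and HSPE1 lay at 0.33, 0.37, 0.35 and 0.41 times the mean of replicates 1 and 3.

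The 6 libraries make 10 splits of 3 against 3, which cannot give a share under 0.05. The real split gave as large a result as any in 1 of 10 splits for called genes (3920, highest other 0), genes higher (2598, highest other 0), genes lower (1322, highest other 0) and enriched terms (112, highest other 0). At an unadjusted p under 0.05, limma gave 5009 genes in the real split and 14 to 210 in the others. For lists called by camera with the preset correlation, 4 of 10 splits gave as many, with 10 in the real split and 7 to 12 in the others. The count of lists called in this way thus does not set the real split apart. Each of the other splits puts NC and sh-circRIMS1 libraries in both arms, which widens the spread within arms and lowers its count of called genes.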
